A study of Caenorhabditis elegans with 24 samples.

How the data were processed

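The samples are 24 RNA libraries of whole adult Caenorhabditis elegans, 3 for each of 8 groups made by strain (N2 or JU2519), time (12 h or 24 h) and exposure. Per the labels' protocols, animals were synchronised by bleaching and at the last larval stage, L4, 50 were moved to a plate that carried 3 animals already infected with Myzocytiopsis humicola, or to a plate free of it, at 25 °C on Escherichia coli OP50. RNA was taken with TRIzol and a column kit and made into stranded mRNA libraries, per the labels' protocols. The strain of the infected animals put on the plates, the sequencing batches and the lanes are not given in the sources used here.

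Reads were aligned with Bowtie2, counted with bedtools and normalized with DESeq2, per the submitters' processing notes; versions, genome build, annotation and the use of strand in counting are not given in the sources used here. The deposited normalized counts (a signal per feature) are read counts divided by 1 size factor per library: within a tolerance of 0.001, every value of a library was a whole multiple of 1 step. That step lies near 1 in JU2519 24 h control replicate 1, where whole reads and rounding are harder to tell apart. For each strain and time the authors also deposited a DESeq2 list of genes with a log2 fold change, a p-value and a false discovery rate. The group in the numerator of those fold changes is not stated, per the file headers. The lists hold 94, 125, 47 and 520 genes for N2 12 h, N2 24 h, JU2519 12 h and JU2519 24 h, and their largest false discovery rates were 0.0989, 0.0987, 0.0927 and 0.0976.

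The table held 23953 features, of which 182 named no gene (0.061% to 0.083% of a library's reads, chiefly repeats) and 23771 named a gene or an isoform. Of these, 23162 matched 19595 genes by name and 609 matched none. Several features stood for 1 gene in 2457 genes (6024 features). Isoforms of a gene and near-identical paralogs can share reads, and so can overlapping genes on opposite strands, so values of single isoforms and of the msp, pud and pals copies are uncertain. Names, transcript lengths and gene neighbours were taken from WBcel235, Ensembl release 115, and no coordinates are given because the authors' build is not stated.

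Samples were grouped by the first letter of their titles, I or C. The label for the exposure state and that letter point the same way in N2 12 h and opposite ways in the other 3 blocks of strain and time (18 libraries). A check set before the data were examined compared I minus C with the authors' lists in every block. The I libraries are called infected and the C libraries control by title on that basis.

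The tests, the rule for naming genes, the 25 gene lists and most alternatives were fixed before the data were examined. Features that name a gene and had at least 10 normalized counts in at least 3 libraries were kept (19508). For these, log2 of the normalized count plus 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). The fit held all 24 libraries, 8 groups and 16 residual degrees of freedom. All tests were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05, and "adjusted p" means this limma value unless another tool is named. The comparisons were infected minus control in each of the 4 blocks, their average, the difference of that effect between strains at each time and between times in each strain, and the strain and time differences among control libraries. The p-values measure only the spread between samples, which were plates of 50 animals. Overlaps of calls between blocks were tested with Fisher's exact test, and no 2 blocks share a library. The fit shares the spread of each feature over all libraries, so calls of different blocks are not fully independent, as that test takes them to be.

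The deposited size factors had been set within each block: the block means of the ratio to a factor over all 24 libraries were 1.09 for N2 12 h, 0.87 for N2 24 h, 1.36 for JU2519 12 h and 0.773 for JU2519 24 h. The strain and time differences among controls were therefore computed on values rescaled by TMM in edgeR 4.0.16, a departure from the fixed design that was made after this scaling was seen. On the deposited scale the median of all features moved by -0.05 between strains and by 0.55 between times.

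Gene lists were tested with camera at a preset correlation of 0.01, with 1 feature (the most abundant isoform) per gene, adjusted over the lists within a comparison, and tested again with an estimated correlation. They were chitinase-like genes, chitinases and chitin synthases, epidermal antimicrobial peptides, p38-dependent intestinal immune genes, C-type lectins, lysozymes and saposins, intracellular pathogen response genes, F-box and MATH genes, cuticle collagens, moulting genes, osmotic stress genes, detoxification genes, heat shock genes, DAF-16 targets with metallothioneins, fasting and fat genes, yolk, oocyte and eggshell, sperm, early embryo, body muscle, neuron and intestine genes, ribosomal proteins, histones and the mitochondrial genome. A member was counted over all genes tested and again with its p adjusted over the list alone. The chitinase-like family was known to have been chosen by the study on these same samples.

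For each infection comparison the genes named are the 8 largest increases and 8 largest decreases among calls with a mean of at least 50 in the higher group, and up to 2 called members of each list by smallest p. In the other comparisons they are the 5 largest per direction, and any measured chil gene could be named. Names outside the rule are said to be so where they occur. Values are means of normalized counts with the standard deviation (SD) of 3 libraries, and log2 changes have their standard error (SE). Ratios and folds were taken from the reads pooled over the 3 libraries of a group and scaled by their summed size factors. They can therefore differ from the ratio of the printed means. A fold against a group with no reads is a lower bound from a floor of 3 reads over the group, and against 1 to 3 reads it has a 95% counting interval. Bounds and intervals cover counting error only, and fitted log2 changes of such genes depend on the added count of 1.

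The tests were run on simulated data with the real means and library sizes before the real values. Of 100 genes changed 2-fold, limma called 74 in N2 12 h, 75 in N2 24 h, 82 in JU2519 12 h, 80 in JU2519 24 h and 96 in the average of the blocks; of 100 changed 4-fold it called 96, 98, 96, 97 and 100. For the strain difference at 24 h it called 53 and 90, and for the time difference in JU2519 55 and 89. These runs held 19113 to 19157 features, and 3.4% to 9.5% of the calls were false. These shares describe the simulated data only. Among the real JU2519 12 h libraries, a split other than the real one called 788 features, against 69 in the real comparison. The simulated shares of recovered and false calls therefore need not hold for the real libraries. Recovery was not worked out apart for genes with few or no reads in controls.

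Alternatives fixed in advance were pseudocounts of 0.5 and 8, no filter, TMM scaling, edgeR's quasi-likelihood test and DESeq2 1.42.0 on recovered reads, the replicate number as a block, an absolute log2 change of at least 1, each library left out, only the 6 libraries of a block, and grouping by the exposure label. Added after the data were seen were leaving out both libraries whose values were shifted with transcript length, summing isoforms, removing the length trend, the deposited scale for the control comparisons, and edgeR and DESeq2 on the 6 libraries of a block. Features naming no gene were left out of the main fit. They were tested in another fit together with the gene features, adjusted over themselves alone, and are reported only as a count. The raw reads were not used here.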

Results

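RNA was sequenced from whole adults of Caenorhabditis elegans that had been kept for 12 h or 24 h on plates with the oomycete Myzocytiopsis humicola, a filamentous pathogen of nematodes, or on plates without it. The laboratory strain N2 and the wild isolate JU2519 were used. The question set by the design is which genes respond to the oomycete in each strain and at each time. There were 24 libraries, 3 for each of 8 groups, each from 50 animals. The total number of reads in a library ran from 6.92 to 67.5 M. In N2 it was 9.63 to 38.6 M in the 12 h infected group, 27.9 to 48.1 in the 12 h controls, 35.5 to 38.6 in the 24 h infected group and 28.8 to 33.2 in the 24 h controls. The JU2519 groups held 6.92 to 41.5 M (12 h infected), 10.7 to 67.5 (12 h controls), 30.2 to 38.4 (24 h infected) and 35.8 to 44.8 (24 h controls). Vitellogenins, the yolk proteins made by egg-bearing adults, took 8.87% to 13.7% of the reads of a library, and the mitochondrial genome 0.17% to 0.77%.

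The labels disagree about which libraries are infected. In N2 12 h the letter in the title (I or C) and the label of the exposure state point the same way. In the other 3 blocks of strain and time (18 libraries) they are opposite. The genes ddn-1, chil-27 and Y71H2AR.2 were higher in the I libraries of all 4 blocks, but most features called in N2 12 h had the opposite sign in JU2519 24 h. Of the 136 features called in N2 12 h, 109 had the same sign in N2 24 h, 124 in JU2519 12 h and 25 in JU2519 24 h. All genes of the authors' own lists had the sign of I minus C: 94 of 94 in N2 12 h, 125 of 125 in N2 24 h, 47 of 47 in JU2519 12 h and 520 of 520 in JU2519 24 h. Fold sizes went together less closely (Spearman rho 0.37, 0.597, 0.403 and 0.0569 in the same order). Of the listed genes, 61, 14, 35 and 73 were called here with that sign. The lists reach false discovery rates above the 0.05 used here, and 74, 93, 40 and 423 of their genes lay below it. The numerator of the authors' folds is not stated. I libraries are called infected and C libraries control on this basis. Values are mean normalized counts ± SD of 3 libraries per group. The authors scaled them within each strain and time, so levels are compared only within a block unless rescaled values are named.

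In N2 at 12 h, uncharacterised genes and cuticle collagens had the largest increases. Y71H2AR.2 had no reads in the controls and 61.4 ± 13.2 in infected animals (at least 73.1-fold higher). B0507.8 stood at 1.07 ± 1.86 and 115 ± 20.7 (ratio of pooled reads, not of these means, 155, counting interval 52.5 to 753). The cuticle collagen genes col-17, dpy-13 and col-125 rose from 1.75 ± 1.83 to 147 ± 60.7, from 7.15 ± 2.0 to 186 ± 52.9 and from a mean of 82.8 to 589.8 ± 82.5. Their log2 changes were 5.93 (SE 0.564), 4.51 (SE 0.677) and 2.83 (SE 0.322), with adjusted p values of 4.44e-06, 0.000877 and 6.06e-05. The collagens col-90 and col-73, the collagen gene dpy-5 and ifas-1 rose by 5.75, 5.57, 5.78 and 5.51 on the log2 scale. Y32F6A.4 fell from 1099 ± 49.0 to 598.7 ± 6.31 (log2 change -0.87, SE 0.131, adjusted p = 0.000876). The gene acox-1.5, which encodes an acyl-CoA oxidase of peroxisomal fat breakdown, fell from 837 ± 24.7 to 601 ± 44.7 (log2 change -0.48, SE 0.0969, adjusted p = 0.0164). The other lower genes were F42A10.7, C13C4.6, catp-5 (isoform b), abt-4, pcp-2 and pmp-1, with log2 changes of -1.12, -0.89, -0.82, -0.67, -0.53 and -0.46.

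By gene list in N2 12 h, 30 of 148 cuticle collagens rose and none fell over all genes tested. Of the same collagens 52 rose and 3 fell when adjusted over the list alone (camera adjusted p = 2e-20; adjusted p = 0.054 with an estimated correlation). In the chitinase-like family, chil-18 (0 in controls, 19.5 ± 3.46, at least 25.3-fold) and chil-27 (1.28 ± 1.58 to 15.7 ± 14.9) rose, 2 of 22 by either adjustment. The study chose that family on these samples, so the count is not independent evidence. The intracellular pathogen response list, genes known from microsporidian and viral infection, had 3 of 34 higher, or 5 adjusted over the list alone (camera adjusted p = 0.00513; adjusted p = 0.236 with an estimated correlation). Among them were pals-39 (isoform a, log2 change 3.36) and pals-28 (at least 9.58-fold). Single members rose in further lists: the epidermal peptide gene fipr-4 (2.91), the C-type lectins clec-17 (ratio 35.9, counting interval 9.48 to 304) and clec-15 (at least 4.35-fold), the saposin-like gene spp-13 (2.71), osr-1 (1.90), the cytochrome P450 gene cyp-34A2 (1.53) and the fatty acid desaturase gene fat-6 (0.34). For fasting and fat genes 5 of 20 rose adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.0968 with an estimated correlation). For epidermal peptides 8 of 45 did (camera adjusted p = 0.00439; adjusted p = 0.62 with an estimated correlation).

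The test for N2 12 h called 128 features higher and 8 lower, which stand for 130 genes. The number depends on single libraries: it was 70 without infected replicate 2, 89 without control replicate 2 and 204 without JU2519 12 h control replicate 1. It was 80 with edgeR, 212 with DESeq2, 67 with a pseudocount of 8 and 11 from the 6 libraries of the block alone. Of the 28 called genes named, Y71H2AR.2, dpy-5, dpy-13 and col-125 stayed past the threshold under all alternatives run. The call of chil-27 ended without infected replicate 3, control replicate 1 or control replicate 3 (adjusted p = 0.174, 0.151 and 0.0872). It also ended with a pseudocount of 8, the replicate number as a block, only the 6 libraries of the block, or both length-shifted libraries left out (adjusted p = 0.18, 0.0719, 0.866 and 0.187). With edgeR the calls of chil-18, clec-17, col-73, fipr-4, osr-1 and spp-13 and of the lower genes C13C4.6, F42A10.7, catp-5 (isoform b), pcp-2 and pmp-1 ended, that of C13C4.6 with TMM and DESeq2 as well.

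In N2 at 24 h the calls of limma were a small set of strongly raised genes. Y71H2AR.2 again had no reads in controls and reached 388 ± 289 (at least 348-fold). B0507.8 rose from 4.70 ± 4.22 to 617 ± 271 and ddn-1 from 29.4 ± 10.8 to 1135 ± 458 (log2 change 5.20, SE 0.316, adjusted p = 2.5e-09). The ratio for droe-8 was 72.3 (counting interval 24.5 to 353), and ifas-1 rose from 10.4 ± 1.99 to 490.5 ± 288. The chitinase-like genes chil-18 (1.47 ± 1.28 to 121 ± 89.1, adjusted p = 0.000976) and chil-27 (1.89 ± 0.75 to 47.7 ± 19.6, adjusted p = 0.00105) rose, as did rabr-4 (log2 change 4.80) and pals-32 (4.46). All 3 infected libraries lay above all 3 controls for each of these genes.

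Intracellular pathogen response genes rose in 4 of 34 cases at 24 h in N2, and in 9 adjusted over the list alone (camera adjusted p = 4.57e-11; adjusted p = 0.00266 with an estimated correlation). The level of pals-28 went from 0 to 34.7 ± 16.8 (at least 31.2-fold). In the chitinase-like family 2 of 22 rose by either adjustment (camera adjusted p = 0.00118; adjusted p = 0.275 with an estimated correlation), again in a family chosen on these samples. The F-box genes fbxa-28 (at least 29.3-fold) and fbxa-116 (isoform b, at least 38.7-fold) rose, 2 of 336. None of 148 cuticle collagens passed with limma, over all genes or adjusted over the list alone, and 10 had an unadjusted p under 0.05 (median log2 change 0.31, camera adjusted p = 0.00797, higher; adjusted p = 0.465 with an estimated correlation). Of 51 sperm genes 0 passed with limma by either adjustment and 21 had an unadjusted p under 0.05 (camera adjusted p = 2.68e-24; adjusted p = 0.275 with an estimated correlation). Their summed level was 7538, 1536 and 468 in the infected libraries and 410, 413 and 345 in the controls. The epidermal peptides likewise had 0 of 45 past the limma threshold and 11 at an unadjusted p under 0.05 (median log2 change 0.77, camera adjusted p = 1.44e-10; adjusted p = 0.192 with an estimated correlation). In all, 21 features (20 genes) were called higher with limma and 0 lower, where 142 lower features had an unadjusted p under 0.05. With edgeR and DESeq2 on all libraries 0 were called lower, and DESeq2 on the 6 libraries of the block called 24 among 160. The authors' list for this block holds 125 genes, 95 higher and 30 lower in the I libraries. Of these, 93 had a false discovery rate below 0.05. DESeq2 on all libraries called 93 features. Of the 12 called genes named, 8 passed under all alternatives run. The call of rabr-4 ended with edgeR (adjusted p = 0.229) and in each test on the 6 libraries of the block, and that of fbxa-116 (isoform b) with edgeR, a pseudocount of 8 and the replicate number as a block (adjusted p = 0.201, 0.297 and 0.0573). The call of pals-32 ended with only the 6 libraries (adjusted p = 0.0708) and that of ifas-1 without infected replicate 3 (adjusted p = 0.0505).

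**Figure D1:**
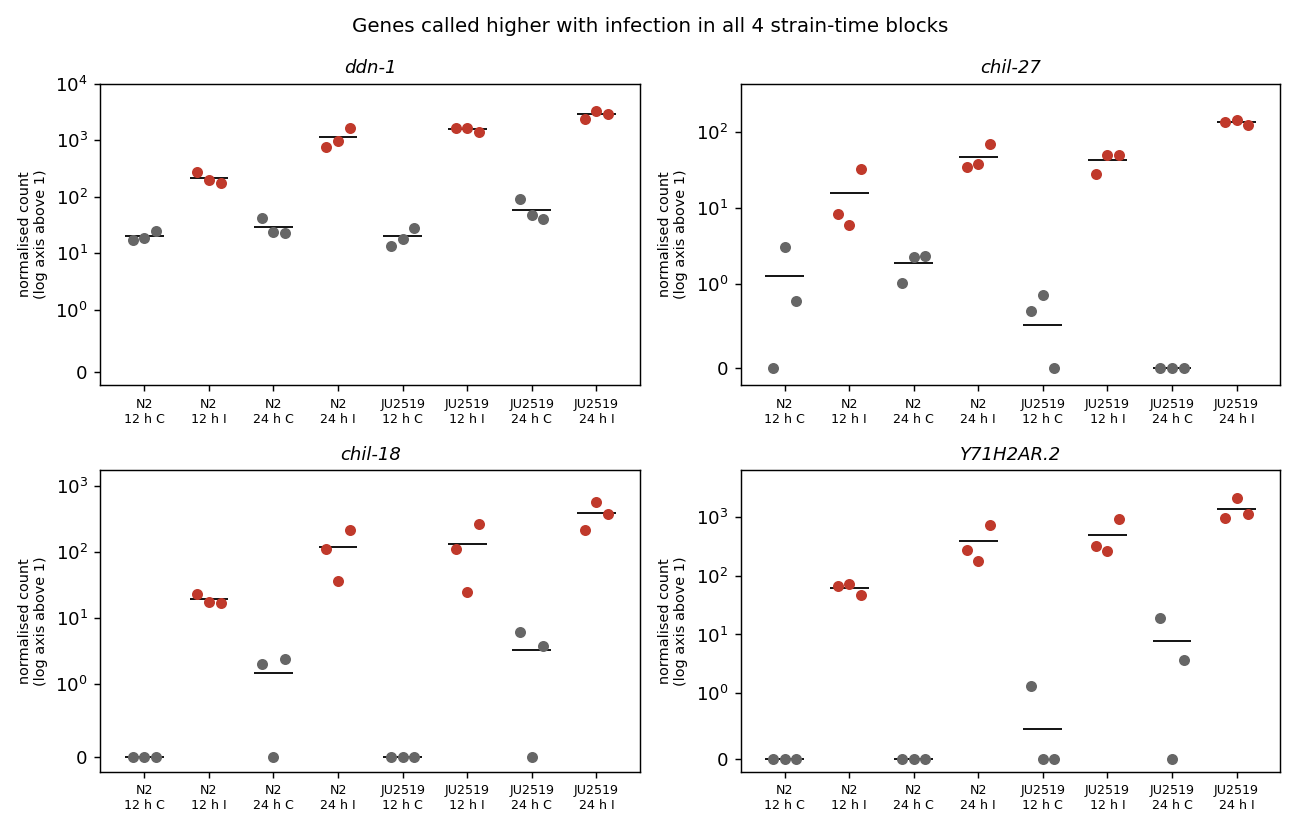
Normalized counts (vertical axis, log scale above 1 and linear below) of ddn-1, chil-27, chil-18 and Y71H2AR.2 in each library of the 8 groups, with control libraries in grey, infected libraries in red and horizontal bars at the group means. Each infected library lies above each control library of its block. Mean ddn-1 in controls and infected animals is 20.3 and 215 in N2 at 12 h and 29.4 and 1135 at 24 h. In JU2519 it is 19.9 and 1572 at 12 h and 59.5 and 2909 at 24 h. Each block was scaled apart, so heights compare only within a block.

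In JU2519 at 12 h the same uncharacterised genes stood out together with collagens. B0507.8 rose from 3.17 ± 2.75 to 843 ± 159 (log2 change 8.02, adjusted p = 6.7e-07). Levels of Y71H2AR.2 went from 0.452 ± 0.782 to 495 ± 352, ifas-1 from 2.49 ± 4.3 to 581 ± 404, and of F15A4.8 (isoform b) from 0 to 224 ± 54.9 (at least 434-fold). The cuticle collagen gene sqt-1 went from 0.226 ± 0.391 to 149 ± 19 (ratio of pooled reads, not of these means, 418, counting interval 115 to 3460). F56A6.5 (at least 274-fold) and chil-18 (0 to 134.5 ± 122, at least 398-fold) rose as well. The nuclear hormone receptor gene nhr-114 (isoform a) fell from 1560 ± 292 to 1136 ± 82.2 (log2 change -0.44, SE 0.0976, adjusted p = 0.048).

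The chitinase-like family had 5 of 22 members higher in JU2519 at 12 h, or 8 adjusted over the list alone, in a family the study chose on these samples. They were chil-27 (0.515 ± 0.456 to a mean of 42.8), chil-18, chil-9 (0.741 ± 0.686 to 96.7 ± 91.1), chil-3 (8.47 ± 3.66 to 36.5 ± 9.91) and chil-1 (isoform b, 5.45 ± 3.05 to 20.3 ± 3.53). Its camera adjusted p was 5.58e-08 (adjusted p = 0.0772 with an estimated correlation). Intracellular pathogen response genes rose in 6 of 34 cases, or 11 adjusted over the list alone (camera adjusted p = 1.66e-10; adjusted p = 0.00349 with an estimated correlation). Among them were pals-26 (log2 change 4.85) and pals-29 (at least 41.4-fold). Of 148 cuticle collagens 13 rose, and 25 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.26e-07; adjusted p = 0.365 with an estimated correlation). Of these, col-17 went from 2.85 ± 2.6 to 244 ± 46.3 and sqt-2 from 3.89 ± 1.14 to 125.5 ± 52.2. The F-box genes fbxa-116 (isoform b, at least 170-fold) and fbxa-28 (counting interval of the ratio 24.2 to 755) rose, 2 of 336 (4 adjusted over the list alone). The gene cyp-14A5 rose from 261.5 ± 12.2 to 469 ± 54.2, the only 1 of 188 detoxification genes over all genes tested (2 adjusted over the list alone). In all, 67 features were called higher and 2 lower, which stand for 66 genes. The count was 41 without infected replicate 2, 155 without control replicate 2 and 7 from the 6 libraries of the block alone. Of the 20 called features named, 4 (Y71H2AR.2, both isoforms of F15A4.8 and sqt-1) passed under all alternatives run. The call of nhr-114 (isoform a) ended with a pseudocount of 8, no filter, edgeR and the replicate number as a block (adjusted p = 0.0506, 0.0534, 0.0518 and 0.105). With that block those of chil-1 (isoform b), chil-3 and chil-9 ended too (adjusted p = 0.0818, 0.0798 and 0.0505).

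**Figure D2:**
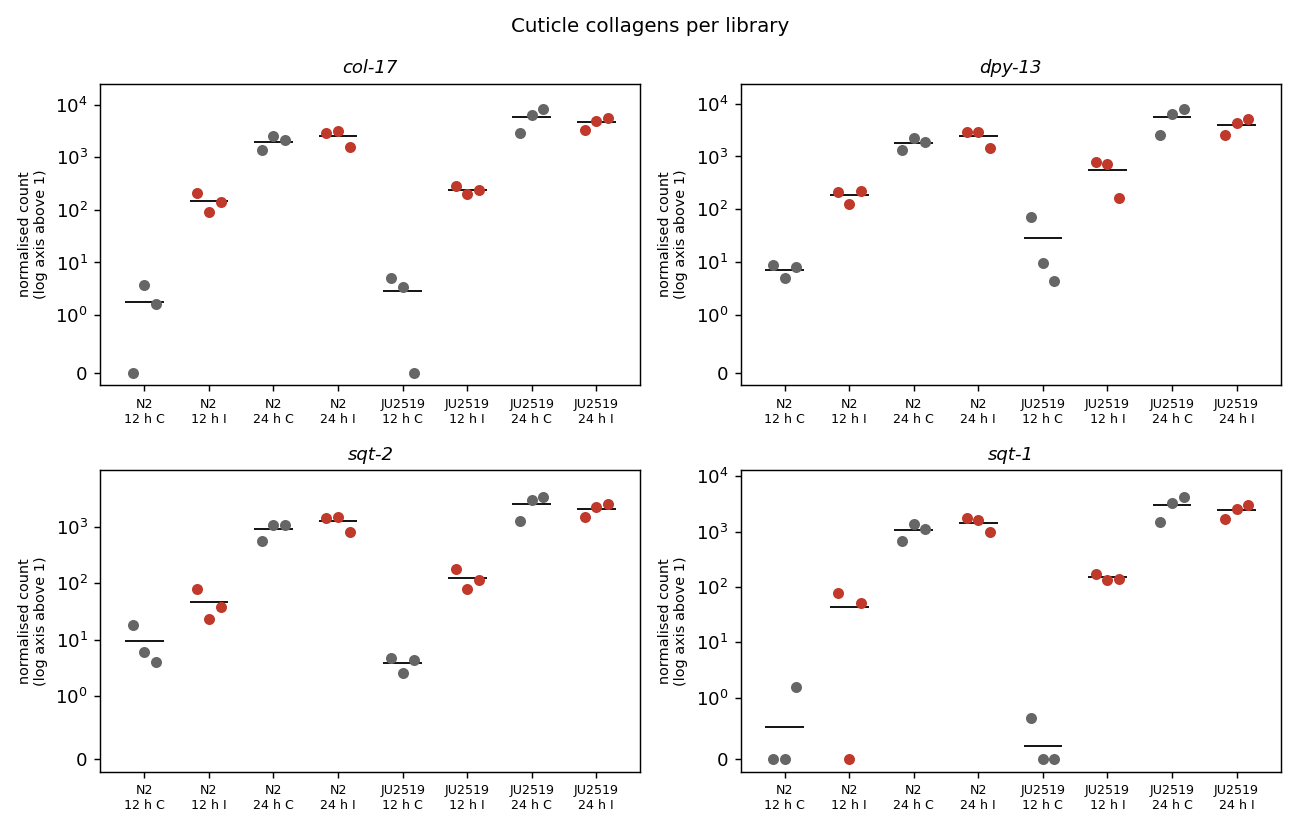
Normalized counts (vertical axis, log scale above 1 and linear below) of the cuticle collagen genes col-17, dpy-13, sqt-2 and sqt-1 per library in the 8 groups, with control libraries in grey, infected libraries in red and horizontal bars at the group means. In N2 at 12 h col-17 has a mean of 1.75 in controls and 147 in infected animals, and in JU2519 2.85 and 244.

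In JU2519 at 24 h single chitinase-like and intracellular pathogen response genes rose, and so did genes of sperm. Y71H2AR.2 rose from 7.65 ± 10.2 to 1376 ± 584, chil-27 from 0 to 136.5 ± 10.1 (at least 150-fold, log2 change 7.10, adjusted p = 2.99e-07) and chil-18 from 3.27 ± 3.06 to 396 ± 183. Y71H2AR.2 (log2 change 8.15) was among the 8 largest increases under the naming rule. The others were in nsph-3.2 (1.3 ± 1.13 to 698 ± 516), the major sperm protein genes msp-36 (ratio 598, counting interval 204 to 2910), msp-79 (1.69 ± 2.92 to 402 ± 304) and msp-40 (ratio 433, counting interval 148 to 2100). With them were the insulin-like gene ins-31 (at least 283-fold) and the C-type lectins clec-94 and clec-110 (at least 243-fold and 199-fold). For all of these but Y71H2AR.2 adjusted p lay between 0.0134 and 0.0454. The collagen gene col-43 fell from 204 ± 9.15 to 98.0 ± 21.6 (log2 change -1.07, SE 0.248, adjusted p = 0.0481).

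Among the lists in JU2519 at 24 h, 5 of 22 chitinase-like genes rose by either adjustment (camera adjusted p = 2.67e-10; adjusted p = 0.031 with an estimated correlation), in a family chosen on these samples. They include chil-9 (2.91 ± 2.53 to 271 ± 149), chil-3 (26.6 ± 12.2 to 135 ± 6.37) and chil-26 (ratio 29.1, counting interval 9.57 to 144). Of 34 intracellular pathogen response genes 7 rose, or 13 adjusted over the list alone (camera adjusted p = 8.2e-12; adjusted p = 0.00187 with an estimated correlation). Of these, pals-28 was at least 89.5-fold and pals-29 at least 57.8-fold higher. Of 51 sperm genes 12 rose, or 45 adjusted over the list alone (camera adjusted p = 5.91e-61; adjusted p = 0.041 with an estimated correlation). Their summed level was 1479 ± 146 in controls and 14910 ± 10100 in infected animals (26520, 8247 and 9951 per library). Of 157 C-type lectins 7 rose, or 31 adjusted over the list alone (camera adjusted p = 7.85e-05; adjusted p = 0.294 with an estimated correlation). All 7, and 29 of the 31, followed the summed sperm level of the libraries (correlation above 0.6 after each group was centred). The F-box genes fbxa-116 (isoform b, ratio 129, counting interval 43.9 to 631) and fbxa-28 (log2 change 4.03) were among 3 of 336 that rose, by either adjustment. The peptide gene fipr-17 (at least 86.4-fold) was the only 1 of 45 epidermal peptides over all genes tested (7 adjusted over the list alone; camera adjusted p = 4.96e-05; adjusted p = 0.384 with an estimated correlation), and it was among the 5 of those 7 that followed the sperm level too. The calls of the chitinase-like, intracellular pathogen response and F-box genes did not (0 of 5, 0 of 7 and 0 of 3). The genes gst-22 (0 to 11.3 ± 1.84) and cyp-14A5 (log2 change 0.59) were the only 2 of 188 detoxification genes (3 higher and 1 lower adjusted over the list alone). For gst-22, which had no read in JU2519 12 h libraries and stood at 2.9% of its N2 level here, RNA of N2 animals in these libraries is not ruled out. Only col-43 fell among 148 cuticle collagens, or 2 adjusted over the list alone (camera adjusted p = 1.05e-07, lower; adjusted p = 0.294 with an estimated correlation).

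The test for JU2519 24 h called 133 features higher and 1 lower, which stand for 132 genes. The levels of 64 of these 134 features followed the summed sperm level of the libraries (correlation above 0.6). The calls of nsph-3.2, msp-36, msp-79, msp-40, clec-110, clec-79 (at least 133-fold) and the sperm gene ssp-35 (log2 change 5.28) ended with edgeR, without both length-shifted libraries and without single libraries of the block. The calls of ins-31, clec-94, fipr-17 and col-43 ended in the same cases and with TMM (adjusted p = 0.0811, 0.0853, 0.0864 and 0.0723), and those of chil-26 and fbxa-28 with edgeR (adjusted p = 0.109 and 0.0553). For msp-36 the single libraries were control replicates 2 and 3 and infected replicates 1 and 3 (adjusted p = 0.0795, 0.0711, 0.0888 and 0.0511). The number of calls was 66, 49 and 56 without control replicates 1, 2 and 3 and 70, 86 and 56 without infected replicates 1, 2 and 3. It was 89 without N2 12 h control replicate 3, 558 and 221 without JU2519 12 h control replicates 1 and 2, 336 without JU2519 12 h infected replicate 3, and 250 and 240 without N2 24 h infected replicates 1 and 3. It was 86 with TMM, 58 with edgeR, 55 without both length-shifted libraries, 229 with the length trend removed, 449 with DESeq2 and 466 with the replicate number as a block. The 6 libraries of the block alone gave 699, of which 608 followed the sperm level. Of the 23 called features named, Y71H2AR.2, chil-27, chil-18, chil-9, pals-28, pals-29, fbxa-116 (isoform b) and gst-22 passed under all alternatives run.

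**Figure D3:**
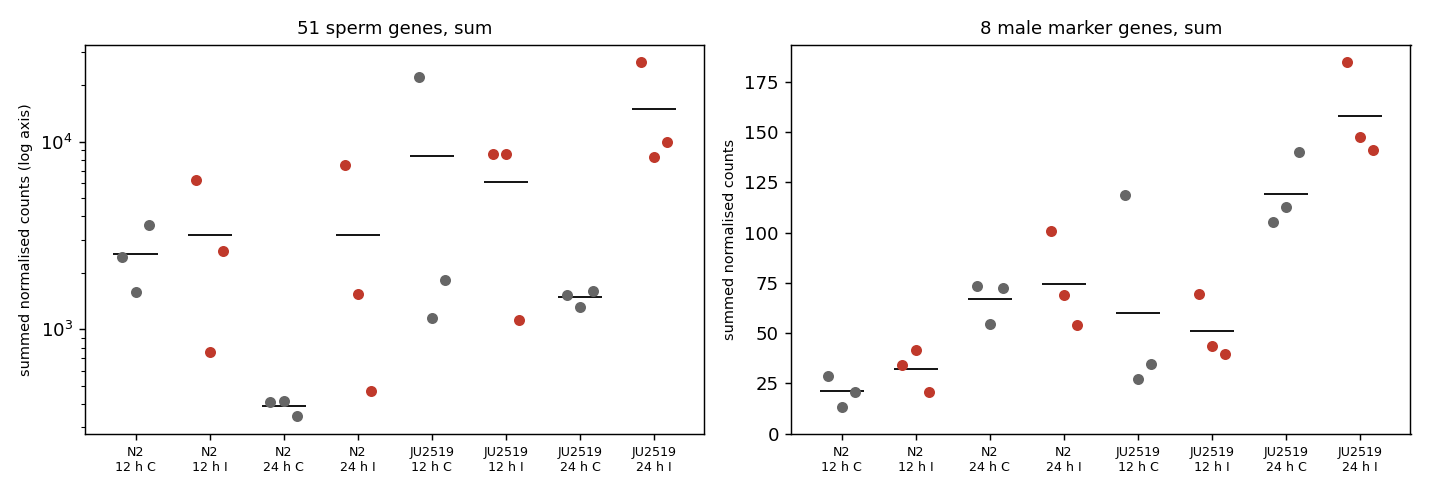
Summed normalized counts of 51 sperm genes (left, log scale) and 8 male marker genes (right, linear scale from 0) in each library of the 8 groups, with control libraries in grey, infected libraries in red and horizontal bars at the group means. For sperm genes the JU2519 24 h infected libraries lie at 26520, 8247 and 9951 and the controls at 1522, 1317 and 1599. The JU2519 12 h controls, in a block scaled apart, spread from 1147 to 22260.

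A set of 13 features, which stand for 12 genes, was called higher in all 4 blocks. They are ddn-1, B0507.8, Y71H2AR.2, F15A4.8 (isoforms a and b), F56A6.5, droe-8, ifas-1, chil-18, chil-27, pals-28, pals-32 and pals-39 (isoform a). Log2 changes of ddn-1 were 3.34, 5.20, 6.30 and 5.67 in N2 12 h, N2 24 h, JU2519 12 h and JU2519 24 h, and those of chil-27 were 2.75, 4.04, 4.86 and 7.10. In every block each infected library lay above each control library for these 13 features. All 21 features higher in N2 24 h were also called higher in JU2519 12 h (0.0721 expected, Fisher's exact p = 5.39e-54) and in JU2519 24 h (0.143 expected, Fisher's exact p = 6.13e-47). The other pairs shared 13 (N2 12 h and N2 24 h, 0.138 expected), 23 (N2 12 h and JU2519 12 h, 0.44 expected), 13 (N2 12 h and JU2519 24 h, 0.873 expected) and 38 (JU2519 12 h and 24 h, 0.457 expected), with Fisher's exact p from 9.61e-67 to 4.12e-12. No lower gene was shared by any pair of blocks. Another 8 features were called in 3 blocks, 27 in 2 and 219 in 1.

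Averaged over the blocks, Y71H2AR.2 (log2 change 7.69, SE 0.365, adjusted p = 8.92e-12), B0507.8 (6.94, SE 0.356), ifas-1 (6.38), chil-18 (5.80, SE 0.39) and F15A4.8 (isoform b, 5.70) had the largest increases. The collagens col-43 (log2 change -0.54, adjusted p = 0.0415) and col-93 (log2 change -0.26, adjusted p = 0.0493) fell. The chitinase-like genes chil-27 (4.69), chil-9 (3.73), chil-3 (1.54) and chil-1 (isoform b, 0.81, adjusted p = 0.0477) rose with chil-18. That is 5 of 22 measured, or 8 adjusted over the list alone, in a family chosen on these samples (camera adjusted p = 1.09e-10; adjusted p = 0.0254 with an estimated correlation). Intracellular pathogen response genes rose in 9 of 34 cases, or 15 adjusted over the list alone (camera adjusted p = 3.6e-18; adjusted p = 0.000155 with an estimated correlation). These 2 lists were the ones whose camera call held with an estimated correlation. In all, 128 features were called higher and 2 lower, which stand for 122 genes. The count was 565 without JU2519 12 h control replicate 1, 243 without JU2519 12 h infected replicate 3, 211 without N2 24 h infected replicate 3, 503 with DESeq2, 210 with the replicate number as a block and 83 at an absolute log2 change of at least 1. The weakest of these calls did not hold elsewhere: col-43, col-93 and chil-1 (isoform b) all ended with no filter (adjusted p = 0.0577, 0.0784 and 0.0684) and with the replicate number as a block (adjusted p = 0.0718, 0.073 and 0.0721). Both collagens also ended with TMM and edgeR, and col-43 and chil-1 (isoform b) without both length-shifted libraries. The call of each gene named here ended or turned with groups taken from the exposure label instead of the title. This follows by construction, since 3 of the 4 blocks then change sign.

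Among the other lists, averaged over the blocks, 19 of 148 cuticle collagens rose and 2 fell (50 and 16 adjusted over the list alone; camera adjusted p = 3.09e-10; adjusted p = 0.16 with an estimated correlation). Epidermal peptides rose in 2 of 45 cases (7 adjusted over the list alone; camera adjusted p = 3.09e-10; adjusted p = 0.16 with an estimated correlation) and C-type lectins in 3 of 157 (4; camera adjusted p = 2.11e-05; adjusted p = 0.16 with an estimated correlation). F-box and MATH genes rose in 3 of 336 (3; camera adjusted p = 0.392) and detoxification genes in 2 of 188 (3; camera adjusted p = 0.482). In the remaining lists limma called 0 members over all genes tested. Of 51 sperm genes 44 passed adjusted over the list alone and 44 had an unadjusted p under 0.05 (camera adjusted p = 4.43e-30; adjusted p = 0.16 with an estimated correlation). Adjusted over the list alone, 2 of 21 heat shock genes rose (5 at an unadjusted p under 0.05; camera adjusted p = 0.00265; adjusted p = 0.16 with an estimated correlation). So did 2 of 9 osmotic stress genes (2 unadjusted; camera adjusted p = 0.105), 1 of 20 fasting and fat genes (2 unadjusted; camera adjusted p = 0.0357; adjusted p = 0.229 with an estimated correlation) and 1 of 32 lysozymes and saposins (2 unadjusted; camera adjusted p = 0.102).

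No member passed by either adjustment with limma in the other 13 lists averaged over the blocks. Moulting genes (17 measured, 5 at an unadjusted p under 0.05) and p38-dependent intestinal immune genes (18 and 2) had positive medians of 0.30 and 0.12, with camera adjusted p of 0.000988 and 0.0352 (adjusted p = 0.311 with an estimated correlation for both). Yolk genes (6 and 1, median -0.08), oocyte and eggshell genes (25 and 0, median -0.04), ribosomal proteins (76 and 0, median -0.03), histones (59 and 0, median -0.05) and the mitochondrial genome (12 and 2, median -0.43) had negative medians. Their camera adjusted p values were 0.00282, 0.00114, 4.79e-05, 0.0352 and 2.07e-06, and with an estimated correlation adjusted p = 0.311, 0.524, 0.585, 0.311 and 0.16. Chitinases and chitin synthases (6 and 0), DAF-16 targets with metallothioneins (11 and 0), early embryo genes (17 and 0), body muscle genes (15 and 1), neuron genes (17 and 1) and intestine genes (12 and 0) had camera adjusted p of 0.395, 0.212, 0.985, 0.908, 0.392 and 0.985.

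Whether the response differed between the strains was tested directly. At 12 h ddn-1 was the only feature called. It rose from 20.3 ± 4.03 to 215 ± 50.4 in N2 and from 19.9 ± 7.6 to 1572 ± 122 in JU2519. The difference was 2.96 on the log2 scale (SE 0.446, adjusted p = 0.0262). That call ended with edgeR, with the replicate number as a block and without both libraries whose values were shifted with transcript length (adjusted p = 0.111, 0.178 and 0.0765). It also ended without any 1 of 9 libraries. These were N2 12 h infected replicates 2 and 3 and control replicates 1, 2 and 3, JU2519 12 h control replicate 2 and infected replicates 1 and 3, and JU2519 24 h infected replicate 3 (0 features called in each case). More were called in other cases: 21 with DESeq2, 8 with a pseudocount of 8 and 2 with the length trend removed. The counts without N2 24 h control replicate 1, N2 12 h infected replicate 1, JU2519 12 h infected replicate 2 and JU2519 12 h control replicate 1 were 2, 4, 5 and 10. At 24 h all 7 calls were larger in JU2519. They were pud-2.2 (the F15E11.1 copy, difference 5.74, SE 0.785, adjusted p = 0.00198), Y94H6A.10 (5.25), pud-1.2 (5.16), Y119D3B.21 (5.14) and gst-22 (3.61, SE 0.373, adjusted p = 5.76e-05). Outside the naming rule, and named after their values were seen, were T28A11.2 (isoform b, 2.77) and Y50D4B.4 (1.03). Except for Y50D4B.4, these genes had near no reads in JU2519 controls (0 for pud-2.2 and gst-22) and high levels in both N2 groups. For instance, pud-2.2 stood at 5548 ± 669 and 5671 ± 419 in N2 controls and infected animals, and at 66.1 ± 44.1 in JU2519 infected animals. The count at 24 h was 2 with edgeR or with the replicate number as a block, 1 with a pseudocount of 8, 3 with TMM or without both length-shifted libraries, and 27 with DESeq2. Calls of Y94H6A.10, pud-1.2 and Y119D3B.21 ended with each of these but DESeq2, and that of gst-22 with a pseudocount of 8 (adjusted p = 0.206). It was 3 without any 1 of the 6 N2 24 h libraries or without JU2519 24 h control replicate 3. It was 4 without N2 12 h infected replicates 1 or 2, N2 12 h control replicates 1, 2 or 3, JU2519 12 h control replicates 2 or 3, or JU2519 24 h control replicate 1. It was 12 and 15 without JU2519 24 h infected replicates 1 and 2.

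**Figure D4:**
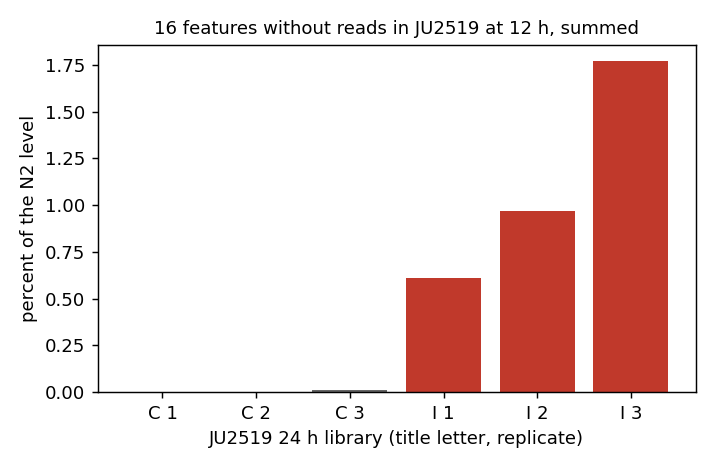
Summed level of 16 features that had no read in any JU2519 12 h library and at least 200 normalized counts on average in N2, as a percent of the N2 level (vertical axis, linear from 0), with 1 bar per JU2519 24 h library, controls (C) in grey and infected (I) in red. The infected libraries lie at 0.612%, 0.97% and 1.77%, and the controls at 0%, 0% and 0.0116%.

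The change of the response between 12 h and 24 h was tested within each strain. In N2 the effect on collagens, on the log2 scale, was smaller at 24 h for col-17 (difference -5.61, adjusted p = 0.00552), col-107 (isoform a, -2.84) and col-125 (-2.58). The same held for abu-8 (-3.85, adjusted p = 0.000362) and Y47D7A.13 (-3.08). At 12 h abu-8 stood at 6.31 ± 0.198 in controls and at a mean of 91.3 in infected animals, and at 24 h at 465 ± 85.4 and 411 ± 126. For col-17 the levels were 1.75 ± 1.83 and 147 ± 60.7 at 12 h, and 2005 ± 580 and 2546 ± 863 at 24 h. With so few reads in the 12 h controls, its log2 change depends on the added count of 1. Y32F6A.4 (1.14) and acox-1.5 (0.83) differed the other way. In JU2519 the effect was smaller at 24 h for the collagens col-17 (-6.60, adjusted p = 0.000418), dpy-13 (-5.24), sqt-2 (-4.82) and col-97 (-2.47) and for Y45G5AM.5 (-2.27). It was larger for pud-2.2 (the F15E11.1 copy, 4.33), gst-22 (3.61) and T28A11.2 (isoform b, 2.90). These stood at 0 in JU2519 24 h controls and at means of 66.1, 11.3 and 6.87 in infected libraries. They are abundant in N2, and RNA of N2 animals in those libraries is not ruled out. By list, where col-107 is represented by its more abundant isoform b, which was not called, 2 of 148 collagens passed in N2, or 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.45e-11; adjusted p = 0.208 with an estimated correlation). In JU2519 4 passed, or 17 lower adjusted over the list alone (camera adjusted p = 5.76e-15; adjusted p = 0.177 with an estimated correlation). With edgeR the calls of col-107 (isoform a), col-125 and Y47D7A.13 in N2 ended (adjusted p = 0.0897, 0.16 and 0.102), and in JU2519 those of dpy-13, Y45G5AM.5, pud-2.2, gst-22 and T28A11.2. The calls of gst-22 and T28A11.2 ended with DESeq2 as well (adjusted p = 0.417 and 0.614). In all there were 7 calls in N2 (2 higher, 5 lower) and 8 in JU2519 (3 higher, 5 lower). The N2 count was 2 without N2 12 h control replicate 3 or N2 24 h control replicate 2, 3 without N2 24 h control replicate 3, and 4 without N2 24 h control replicate 1 or infected replicates 1 or 3. It was 18 without N2 12 h infected replicate 1 or JU2519 12 h control replicate 1, 4 with edgeR, 19 with the replicate number as a block and 73 with DESeq2. The JU2519 count was 4 without N2 24 h control replicate 2 or JU2519 24 h control replicates 2 or 3, 5 without N2 12 h control replicates 1 or 3, N2 24 h control replicates 1 or 3 or any N2 24 h infected replicate. It was 14 without JU2519 12 h infected replicate 3, 20 without JU2519 24 h infected replicate 2, 5 with edgeR, 4 without both length-shifted libraries or with isoforms summed, 17 with the replicate number as a block and 91 with DESeq2.

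The strains differed widely without infection. On TMM-scaled values C14C6.12 was higher in JU2519 controls (491 ± 79.3 and 645 ± 128 at 12 h and 24 h, against 5.29 ± 3.27 and 4.07 ± 3.53 in N2; log2 difference 6.92, SE 0.416, adjusted p = 1.41e-11). Next came C36C5.4 (6.74), ZK105.3 (6.61), scl-25 (6.18) and C29F9.11 (5.82). The pud genes, named for proteins raised in daf-2 insulin receptor mutants, were lower in JU2519. The gene pud-1.1 stood at 3770 ± 862 and 4855 ± 306 in N2 and 0.697 ± 0.62 and 0 in JU2519 (log2 difference -11.71, SE 0.593, adjusted p = 6.74e-13). Log2 differences were -12.10 and -11.86 for the 2 copies of pud-2.2 (F15E11.14 and F15E11.1), -11.91 for pud-1.2 and -11.96 for Y119D3B.21. Reads of a wild isolate were counted on a reference whose strain is not stated, so genes that differ in sequence between the strains can appear low or absent. Among lists, 75 of 148 collagens were higher and 8 lower in JU2519 (77 and 8 adjusted over the list alone; camera adjusted p = 2e-10; adjusted p = 0.206 with an estimated correlation). Higher too were 14 of 17 moulting genes (camera adjusted p = 1.71e-05; adjusted p = 0.464 with an estimated correlation), 14 of 15 body muscle genes (camera adjusted p = 2.91e-09; adjusted p = 0.191 with an estimated correlation) and 13 of 17 neuron genes (camera adjusted p = 1.01e-05; adjusted p = 0.138 with an estimated correlation), each with 14 adjusted over the list alone. In all, 3813 features were higher and 3564 lower (3426 and 5004 on the deposited scale), which stand for 6396 genes.

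With time, collagens rose in the controls of both strains together. On TMM-scaled values averaged over the strains, the collagen genes sqt-1 (log2 difference 10.03, SE 0.693, adjusted p = 7.63e-10), col-17 (9.84), col-90 (9.14), rol-6 (8.79) and col-41 (8.72) were higher at 24 h than at 12 h. Levels of col-17 were 1.93 ± 2.02 and 1762 ± 508 in N2 and 3.85 ± 3.49 and 4654 ± 2270 in JU2519. Genes of sperm were lower at 24 h: msp-36 (log2 difference -5.72, SE 1.09, adjusted p = 0.000452), msp-79 (-5.69) and msp-81 (-5.61), along with R09E10.6 (-6.07) and nsph-3.2 (-5.60). In JU2519 this rests largely on 12 h control replicate 1, where the summed sperm level was 22260, against 1147 and 1832 in the other 12 h controls. Without that library the difference of msp-36 was -4.77 (adjusted p = 0.00125) and that of msp-81 -4.52 (adjusted p = 0.0209). Of 148 collagens 81 were higher and 33 lower (82 and 36 adjusted over the list alone; camera adjusted p = 3.51e-05; adjusted p = 0.385 with an estimated correlation). By contrast, 42 of 51 sperm genes were lower (45 adjusted over the list alone; camera adjusted p = 1.63e-15; adjusted p = 0.385 with an estimated correlation). Moulting genes were higher in 14 of 17 cases (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.21e-10; adjusted p = 0.127 with an estimated correlation). The p38-dependent intestinal immune genes were higher in 14 of 18 (14; camera adjusted p = 5.43e-06; adjusted p = 0.127 with an estimated correlation). In all, 3372 features were higher and 2105 lower at 24 h, which stand for 4769 genes. On the deposited scale, which was set within each block, the split was 15336 higher and 384 lower.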

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

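All tests of explanations in this part, and the counts over other splits of the samples, were chosen only after the results had been seen, while the 4 tests of a difference between effects were fixed in advance.

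The effect of infection differed between strains or times in 4 tests, which is why these genes are listed again here. At 12 h 1 feature differed between strains, ddn-1 (2.96 on the log2 scale, larger in JU2519). At 24 h 7 did, of which the named ones are pud-2.2 (the F15E11.1 copy, 5.74), Y94H6A.10 (5.25), pud-1.2 (5.16), Y119D3B.21 (5.14) and gst-22 (3.61). Between 12 h and 24 h in N2 7 features differed: Y32F6A.4 (1.14), acox-1.5 (0.83), col-17 (-5.61), abu-8 (-3.85), Y47D7A.13 (-3.08), col-107 (isoform a, -2.84) and col-125 (-2.58). In JU2519 8 did: pud-2.2 (the F15E11.1 copy, 4.33), gst-22 (3.61), T28A11.2 (isoform b, 2.90), col-17 (-6.60), dpy-13 (-5.24), sqt-2 (-4.82), col-97 (-2.47) and Y45G5AM.5 (-2.27).

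Chance cannot be excluded for the size of any of these 4 counts. Of 100 splits of the same libraries, 41 gave as many calls as the strain difference at 12 h (1 call, highest other 675), and 8 as many as the strain difference at 24 h (7 calls, highest other 64). For the time difference 10 splits gave as many in N2 (7 calls, highest other 76) and 11 in JU2519 (8 calls, highest other 1094). A split that swaps infected and control libraries in 1 block alone adds the infection effects of the blocks instead of subtracting them. In N2 the highest other count, 76, equals the count with groups from the exposure label, which swap the 24 h block alone. Splits with several times the real count can therefore hold the infection effect itself. For that reason the shares of splits are not a measure of chance alone, and no structure of the samples is concluded from them.

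The genes that differed between strains at 24 h include transcripts abundant in N2 and near absent in JU2519. Of 16 features with no read in any JU2519 12 h library and a mean of at least 200 in N2, 15 had reads in the JU2519 24 h infected libraries and 1 in the controls. The tables argue against reads passed alike between all libraries at 24 h, since the controls held 0.00385% ± 0.00668 of the N2 level and the infected libraries 1.12% ± 0.594 (SD, n = 3 each). At 12 h the difference was weaker: of 29 features chosen on the JU2519 24 h controls, 11 had reads in infected and 6 in control libraries (0.19% ± 0.189 and 0.00871% ± 0.0115), and the lowest infected library (0.0132%) lay below the highest control (0.0218%). RNA of N2 animals in the infected JU2519 24 h libraries cannot be told apart from a true difference in the response between the strains. The 15 features had reads in 8, 12 and 14 cases per library, at 0.311% to 2.9% of the N2 level. All 16 did not share 1 common percentage (chi-square 111, 15 degrees of freedom, p = 8.68e-17). That test allows for counting error only. Replicates of 1 group differed by 4.08 to 91 chi-square per degree of freedom across features. That range includes features with many reads, where the same relative spread adds more to chi-square. It is no measure for these 16, which had 0 to 32 reads over the infected libraries. The test therefore cannot say whether the unlike percentages count against RNA of N2 animals. The strain and the transcripts of the infected animals put on the plates are not given.

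Collagens called higher at 12 h and not at 24 h make up much of the time differences. Of the features called higher at 12 h, 89.1% (114 of 128) in N2 and 40.3% (27 of 67) in JU2519 rose by over 1 on the log2 scale between the 12 h and 24 h controls of the other strain, against 10.8% and 6.8% of all features, so infected animals further along in age than their controls may account for them. In N2 at 12 h 82.1% of collagens (69 of 84) lay above features matched on level and on the age change of the other strain. In JU2519 at 12 h 49.3% did (37 of 75, binomial SE 5.77), and at 24 h 63.1% in N2 and 28% in JU2519. The match cannot tell a collagen change beyond the age trend from age alone, since some collagens rose by unlike amounts in the strains' controls. On TMM-scaled values col-125 went from 91.2 to 1917 in N2 controls and from 1073 to 7037 in JU2519 controls. The transcript length shift of N2 12 h infected replicate 3 is excluded as the whole cause, since 23 of the 30 collagen calls remained without it and the other shifted library. Infection itself, a difference in the age of the animals by plate and causes not tested here all stay open for the collagens.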

How the results depend on the processing

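The direction of each named gene that was called held under the alternatives run, apart from groups taken from the exposure label, which change the sign of 3 blocks by construction. Directions of named genes that were not called were not followed in this count. Calls moved more than directions: of all tested values of named called genes, those that fell short of the threshold numbered 194 of 1061 in N2 12 h, 20 of 455 in N2 24 h, 71 of 755 in JU2519 12 h, 142 of 873 in JU2519 24 h and 71 of 394 in the average, and 12 of 36, 61 of 179, 40 of 251 and 81 of 286 in the strain difference at 12 h and 24 h and the time difference in N2 and JU2519. All 348 and 350 such values in the strain and time differences of controls held. The alternatives that leave out both length-shifted libraries, sum isoforms, remove the length trend, use the deposited scale for controls, or run edgeR and DESeq2 on the 6 libraries of a block were chosen after seeing the data. Where no reason is given, the cause was not tested. Libraries as shallow as 6.92 M reads limit what can be said of genes with few reads, for which folds are bounds.

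With a pseudocount of 8, N2 12 h gave 67 calls, the strain difference 8 at 12 h and 1 at 24 h. TMM gave 86 in JU2519 24 h and 3 in the strain difference at 24 h, and the deposited scale 15720 in the time difference of controls, where the scale itself shifts all features. Using edgeR gave 80 in N2 12 h, 58 in JU2519 24 h, 0 and 2 in the strain differences and 4 and 5 in the time differences in N2 and JU2519. DESeq2 gave 212 in N2 12 h, 93 in N2 24 h, 449 in JU2519 24 h, 503 in the average, 21 and 27 in the strain differences, and 73 and 91 in the time differences. A log2 change of at least 1 left 83 in the average and 2084 and 2050 in the strain and time differences of controls. From the 6 libraries of a block, limma gave 11 in N2 12 h, 7 in JU2519 12 h and 699 in JU2519 24 h; edgeR gave 36, 32, 13 and 684 in N2 12 h, N2 24 h, JU2519 12 h and JU2519 24 h, and DESeq2 160 in N2 24 h and 958 in JU2519 24 h. Without both length-shifted libraries there were 55 in JU2519 24 h, 0 and 3 in the strain differences and 4 in the time difference in JU2519. Summed isoforms gave 4 in that last comparison, and removal of the length trend 229 in JU2519 24 h and 2 in the strain difference at 12 h. With an estimated correlation the gene lists past the threshold went from 8 to 0 in N2 12 h, 13 to 1 in N2 24 h, 8 to 1 in JU2519 12 h, 9 to 3 in JU2519 24 h and 15 to 2 in the average.

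Leaving out each library in turn gave 70 to 204 calls in N2 12 h, 16 to 24 in N2 24 h, 41 to 155 in JU2519 12 h, 49 to 558 in JU2519 24 h and 99 to 565 in the average. The strain difference gave 0 to 10 at 12 h and 3 to 15 at 24 h, and the time difference 2 to 18 in N2 and 4 to 20 in JU2519. Among controls the range was 6424 to 8236 for strain and 4353 to 6342 for time. Where a library of the group itself is left out, fewer samples are compared.

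With groups from the exposure label the average gave 63 calls, the strain difference at 12 h 212 and the time difference in N2 76. In the average the reversed values were Y71H2AR.2 -4.72, B0507.8 -3.86, ifas-1 -3.62, chil-18 -3.63, F15A4.8 (isoform b) -3.78, col-43 0.52, col-93 0.14, chil-1 (isoform b) -0.94, chil-3 -1.23, chil-27 -3.31 and chil-9 -3.21. The strain difference of ddn-1 at 12 h was -9.63, and at 24 h it was -5.74 for pud-2.2 (the F15E11.1 copy), -5.25 for Y94H6A.10, -5.16 for pud-1.2, -5.14 for Y119D3B.21 and -3.61 for gst-22. The time difference in JU2519 was -4.33 for pud-2.2, -3.61 for gst-22, -2.90 for T28A11.2 (isoform b), 6.60 for col-17, 5.24 for dpy-13, 4.82 for sqt-2, 2.47 for col-97 and 2.27 for Y45G5AM.5.

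Whether samples with the same replicate number share more than that number is not settled. The correlation of deviations between same-numbered samples ran from -0.101 to 0.299, and not all were above 0.1. For replicate 1 it was 0.276 in JU2519 12 h and 0.299 in JU2519 24 h. There, and for replicates 2 and 3 in N2 24 h, the same-numbered control was the best match, and for the others it was not. With the replicate number as a block there were 466 calls in JU2519 24 h, 210 in the average, 2 in the strain difference at 24 h, 19 and 17 in the time differences in N2 and JU2519, and 2358 and 2915 in the strain and time differences of controls. The block gave 139, 22 and 74 calls in N2 12 h, N2 24 h and JU2519 12 h, and 1 call in the strain difference at 12 h, which is another feature than ddn-1 (0 shared).

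Other splits of the samples argue against chance as the source of the count in the average (130 calls, highest other 9 in 100 splits, 1 as large with the real one). The same holds for the strain difference of controls (7377, highest other 4238, 1 as large) and the time difference of controls (5477, highest other 1855, 1 as large). Strain and time coincide with the blocks, so splits of controls cannot tell them from a difference in handling between blocks. In a single block there are 10 splits, too few for a share under 0.05: the real and highest other counts were 136 and 13 in N2 12 h, 21 and 0 in N2 24 h, 69 and 788 in JU2519 12 h, and 134 and 0 in JU2519 24 h.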

Other observations

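Of the tests in this part, the one for males was written before its result was seen and the others only after.

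Sperm genes varied between libraries of the same group as well as with infection. The summed level of 51 sperm genes was 3203 ± 2780 in infected and 2536 ± 1010 in control N2 animals at 12 h, 3181 ± 3810 and 389 ± 38.5 at 24 h, 6114 ± 4330 and 8414 ± 12000 in JU2519 at 12 h, and 14910 ± 10100 and 1479 ± 146 at 24 h (SD, n = 3 each). In the JU2519 12 h controls 1 library stood at 22260 and the others at 1147 and 1832, and the infected libraries were at 8619, 8608 and 1115. One split of that block, control replicate 1 with infected replicates 1 and 2 against the rest, called 788 features, of which 696 followed the sperm sum, against 69 in the real comparison.

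Males among the animals are a candidate explanation for the sperm levels, written before the test. Across the 24 libraries, with each group centred, the sum of 8 male marker genes rose with the sperm sum (Pearson r = 0.663, permutation p = 0.0298; Spearman rho = 0.563, permutation p = 0.0352; 100000 permutations within groups, 1 relation tested), and r was 0.461 without the 2 libraries farthest from the median. In JU2519 at 24 h the marker sum was 185, 147 and 141 in infected libraries and 105, 113 and 140 in controls, so all infected libraries lay above all controls. Animals of the 12 h kind among the 24 h animals cannot be told apart from this, since on TMM-scaled values the mean sperm sum of JU2519 24 h infected libraries was 1.01 times that of the JU2519 12 h controls (11430 ± 7510 and 11270 ± 16000), a mean set by 1 library. The rise of sperm genes with infection in JU2519 at 24 h passed its test (12 of 51 genes), and whether infection itself brought it stays open.

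Between blocks, the correlation of infected minus control across 12897 features was 0.494 for N2 12 h with JU2519 12 h, 0.255 for N2 12 h with N2 24 h, 0.287 for N2 24 h with JU2519 12 h, 0.0412 for N2 24 h with JU2519 24 h, 0.008 for JU2519 12 h with JU2519 24 h and -0.255 for N2 12 h with JU2519 24 h. These are across genes, which are not independent replicates. In N2 12 h infected replicate 3 and JU2519 24 h control replicate 3 the deviation from the group mean fell with transcript length (Spearman rho -0.688 and -0.609 across features), and the 2 deviations correlated at 0.688, or 0.484 after the length trend was removed. Of 109 tested features that name no gene, limma called 0 in each infection comparison, with 12, 3, 7 and 5 at an unadjusted p under 0.05 in N2 12 h, N2 24 h, JU2519 12 h and JU2519 24 h.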
